A study of Mus musculus with 4 samples.

How the data were processed

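The data were 4 RNA sequencing libraries of liver double negative T cells, 2 from mice on a normal diet and 2 from mice on a methionine-choline deficient diet. Per the labels' protocols, RNA was extracted with Trizol from sorted cells and libraries were made with an Illumina TruSeq kit. The deposited values were taken as FPKM, a unit scaled by transcript length and mapped fragments. Neither the table nor the labels name that unit; it was chosen because the values are not whole, reach far below 1 and sum to between 370112 and 389403 per library. A table of TPM values would differ by a factor per library. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build mm8 were used; the quantifier, annotation and filters are not given in the sources used here. The table gives gene symbols without coordinates, and no coordinates are printed. Of its 17454 rows 245 carry a suffix for repeated loci and 1597 are 0 in all libraries.

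Samples were grouped by the diet in the labels, and columns were matched to samples by title. No whole read counts can be read from these values, so no count test was run and the depth and the precision it gives are unknown. Genes that every cell uses are sometimes listed at 0, so a 0 is given as listed and not as absence. Values were analysed as log2(FPKM + 1), for the 10423 genes with at least 1 FPKM in at least 2 libraries, with limma 3.58.1 in R 4.3.3 (a mean-variance trend, diet as the single factor, Benjamini-Hochberg adjusted p of 0.05). The fit had 2 residual and 2.84 prior degrees of freedom. The log2 scale with a pseudocount of 1 understates changes of low genes. Folds are ratios of mean FPKM. Tested on simulated data with 200 changed genes among 10423 in 20 runs, the limma step recovered 9.17% of changes of 1 log2 unit, 71.8% of changes of 2 and 91.9% of changes of 3, with 5.55% of calls false, and with no changed genes limma called 0 on average, with 521.35 at an unadjusted p under 0.05. The changed genes were drawn from those with a mean log2 value above 2, and noise was drawn independently for each gene and library. These rates therefore do not cover low genes or deviations that many genes of a library share.

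A set of 34 gene lists was fixed before the data were examined, as were the main test, the alternatives and the rule for named genes. Lists with at least 5 tested members (33 of 34; markers of mast cells and basophils had too few) were tested with limma's camera with a preset inter-gene correlation of 0.01, with camera with an estimated correlation, and with fry. None of the 11 lists past the threshold with the preset correlation held with an estimated one, where the smallest camera adjusted p was 0.268. That variant tests on the 2 residual degrees of freedom, so it had little power here. A high correlation was not needed for the loss. Interferon-stimulated genes, with an estimated correlation of -0.026, also had a camera adjusted p of 0.268. For the rest of the 11 lists the estimate lay above the preset 0.01. It was 0.916 for B cell, 0.483 for T cell identity, 0.474 for type 17, 0.352 for ribosomal and 0.304 for cytotoxic genes. For conventional cell, natural killer receptor, type 1, cell cycle and naive lists it was 0.181, 0.162, 0.052, 0.047 and 0.032. Adjusted p with the preset correlation may therefore be too small for these lists. The rule named the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap, up to 4 members per list with called members first and any further called member, a fixed panel (with Cd3e, Cd4, Cd8a, Klrb1c, Trdc, Il17a, Ifng, Tnf, Gzmb, Gzma, Prf1, Fasl, Bcl2, Mki67, Alb, C1qa and Cd79a), and the 2 most abundant genes per list of other cell types. Some genes that the rule names are not reported here. Cd8b1, Ncr1, Pnlip, Ctrb1, Gimap4, Try4, Try5, Tyrobp, Fcer1g, Samd3 and Osbpl5 lie outside the rule and were chosen after their values were seen.

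The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, quantile normalization, centring on the median, leaving out each library, the replicate number as a block, limma without the trend, an adjusted p of 0.10, an absolute log2 change of 2, and a Spearman correlation. Leaving out the genes of other cell types, robust empirical Bayes and counts of list members with 1 library left out were added after seeing the data. Shares of sequence words of 36 bases found in no other gene were counted in the transcripts of GENCODE vM21, which is not the authors' annotation, for 129 genes, and correlations with FPKM were tested with 100000 permutations.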

Results

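RNA was sequenced from double negative T cells of the mouse liver, which carry the T cell marker CD3 but neither CD4 nor CD8. Live cells positive for CD45 and CD3 and negative for NK1.1, CD4 and CD8 had been sorted by flow cytometry from adult C57BL/6 mice. The mice had received a normal diet or a methionine-choline deficient diet, a diet widely used to produce fatty liver inflammation in mice, and each diet was represented by 2 libraries. The labels do not say whether the libraries of a diet came from separate animals, so p-values measure only the spread between these libraries. The table held 17454 gene rows with values taken as FPKM, which summed to 389403 and 370112 in the normal diet libraries and to 373642 and 384322 in the deficient diet libraries. Read depth is unknown, since FPKM values keep no read counts. Between 9712 and 10435 genes reached 1 FPKM in a library. Across the 10423 genes with at least 1 FPKM in at least 2 libraries, the log2 values correlated with Pearson's r = 0.938 between the normal diet libraries and 0.963 between the deficient diet libraries. Between diets r ran from 0.893 to 0.933, a description across genes, which are not independent replicates. The first principal component held 59.4% of the variance and separated the diets. The second held 29.5% and set apart the libraries within each diet. Its scores were 30.3 and -34.6 for normal diet replicates 1 and 2, and -14.4 and 18.8 for deficient diet replicates 1 and 2.

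The comparison asked how gene expression of these T cells differed between the diets. In the deficient diet libraries 16 of 24 gamma-delta T cell and type 17 genes rose, among them the cytokine gene Il17a. By contrast, 5 of 14 killing genes, 7 of 23 natural killer receptor genes, 18 of 36 cell cycle genes and the cytokine gene Ifng fell. As sets, none of these lists passed with an estimated correlation (adjusted p = 0.568 for type 17, killing and natural killer receptor genes and adjusted p = 0.268 for cell cycle genes). Markers of conventional CD4, CD8 and natural killer cells were lower together with the killing genes (camera adjusted p = 0.00244 with a preset correlation, adjusted p = 0.568 with an estimated correlation), and Cd8a and Klrb1c, which did not pass, had log2 changes of -2.80 and -1.76. Il17a rose from 74.1 ± 37.2 to 420.4 ± 22.1 FPKM (mean ± SD, n = 2 per diet, as for all means here), and Ifng fell from 1160 ± 527 to 82.6 ± 12.5 FPKM. In limma, with changes on the log2(FPKM + 1) scale, 286 of the 10423 genes passed a Benjamini-Hochberg adjusted p of 0.05, 127 higher and 159 lower on the deficient diet, and the smallest adjusted p was 0.0180. Without regard to that test, 1198 genes lay at least 1 log2 unit apart with both libraries of 1 diet above both of the other, 500 higher and 698 lower. Such separation was seen in 56.2% of tested genes, where chance gives 33.3% on average. Genes are not independent, so the gap between these shares is a description and not a test. The count of 286 changed with each library left out: 352 genes passed without normal diet replicate 2 (176 of them among the 286), and none passed in limma without normal diet replicate 1 or without either deficient diet replicate, where 1670, 2029 and 1337 genes had an unadjusted p under 0.05. With 1 library left out, the fit takes its spread from the 2 libraries of the other diet alone. It then has less power, so a loss of calls does not by itself show dependence on the library left out. All 286 were also lost without a filter on low values, where 2712 genes had an unadjusted p under 0.05.

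Of the 10 called genes with the largest rises, Ccr8, a chemokine receptor, rose from 36.9 ± 0.398 to 317.6 ± 12.9 FPKM, a change of 3.07 ± 0.13 (SE) on the log2 scale with an adjusted p of 0.0180. Ramp1 and Ramp3, which encode proteins that pair with the calcitonin receptor-like receptor, rose 8.36-fold and 7.38-fold by mean FPKM. Itgae, the integrin CD103, rose from 9.87 ± 3.88 to 75.3 ± 17.3 FPKM, and Ret, a receptor tyrosine kinase, from 1.49 and 0.672 FPKM to 15.7 and 18.2 FPKM. Chad, Dkk3 and Fam83a rose 22.7-fold, 10.1-fold and 8.58-fold. Olfr60 rose 35.3-fold from 0.479 and 0.265 FPKM, values near 0 that inflate the fold. Its log2 change was 3.34, against 4.18 for Chad. Rnf208 was listed at 0 and 0.195 FPKM on the normal diet and at 19.3 and 20.9 FPKM on the deficient diet. Among the 10 largest falls, Klre1, a receptor of natural killer cells, fell from 143.4 ± 8.69 to 6.14 ± 2.27 FPKM, a log2 change of -4.38 ± 0.26 with an adjusted p of 0.0290. Cd160 fell from 148.8 ± 53.1 to 8.68 ± 0.479 FPKM, Gimap7 from 288.7 ± 36.7 to 22.5 ± 5.33 FPKM, and Klrg1 from 64.3 ± 19.5 to 4.64 ± 1.62 FPKM. Art2b, an ADP-ribosyltransferase gene with a close copy, fell from 46.2 ± 16.3 to 1.30 ± 0.449 FPKM, Alyref from 80.9 ± 16.1 to 6.28 ± 3.47 FPKM, and Gm14446, which belongs to a family of similar genes and is uncertain for that reason, from 43.2 ± 11.9 to 2.83 ± 0.305 FPKM. Ifng and Gzmb belong to the same 10, as does Cela2a, an elastase of the exocrine pancreas, at 1538 ± 849 against 76.9 ± 32.3 FPKM.

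The type 17 list was the list with the most rises. The gamma-delta T cell and type 17 list holds 32 genes, of which 24 were tested. Of these 24, 16 rose and none fell over all genes tested, and 21 rose adjusted over the list alone. Il23r, the receptor for interleukin 23, rose from 11.9 and 27.5 FPKM in the normal diet libraries to 116.2 and 123.9 FPKM in the deficient diet libraries. Il1r1 rose from 8.12 ± 3.22 to 53.3 ± 12.6 FPKM. Blk, a kinase of interleukin 17-producing gamma-delta T cells, rose from 41.4 ± 17.7 to 235.5 ± 41.5 FPKM, and Il17re from 30.2 ± 7.96 to 166.1 ± 11.7 FPKM. Il18r1, Kcnk1, Tmem176b, Serpinb1a, Ccr6 and Rora also rose, by 4.99-fold, 5.11-fold, 5.08-fold, 6.13-fold, 4.01-fold and 3.11-fold. Il17f had 7.64 ± 3.61 against 36.2 ± 4.16 FPKM and did not pass (adjusted p = 0.0511). As a set the list was higher by camera with a preset correlation (adjusted p = 3.5e-15) and did not pass with an estimated correlation (adjusted p = 0.568). As for the 286 calls together, whether members passed depended on which library was left out. The median log2 change ran from 1.98 without normal diet replicate 1 to 2.38 without normal diet replicate 2. At least 22 of 24 stayed higher by fitted value with 1 library left out. That count was largely fixed, since 22 of 24 members had libraries of the diets that did not overlap.

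**Figure D1:**
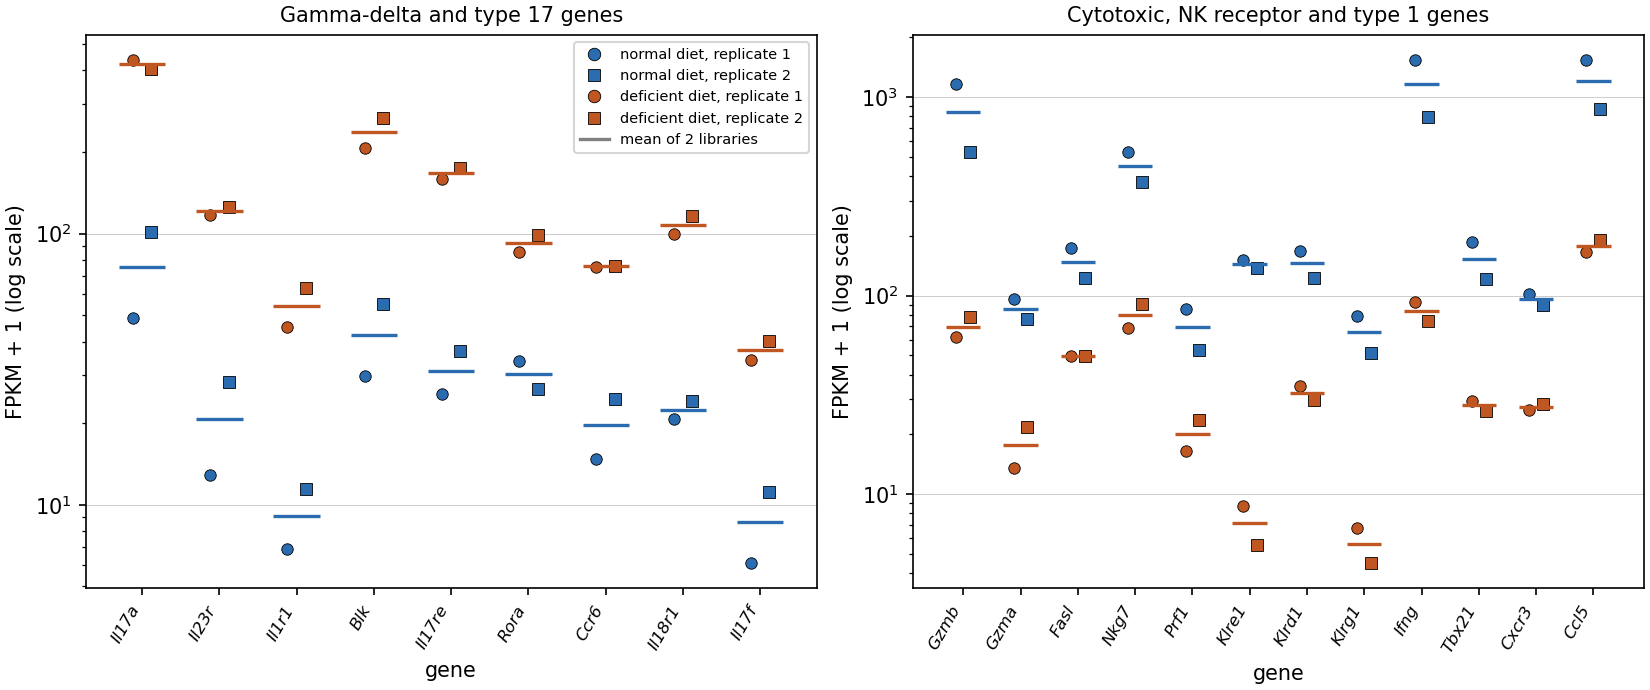
FPKM + 1 on a log axis for gamma-delta T cell and type 17 genes (left) and for cytotoxic, natural killer receptor and type 1 genes (right). Circles and squares mark the libraries and a line the mean of 2 libraries per diet. In the left panel both deficient diet libraries lie above both normal diet libraries for each gene plotted, Il17f not having passed the test, and in the right panel both lie below, Prf1 not having passed.

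Genes of killing, of natural killer receptors and of the type 1 program were lower on the deficient diet. In the cytotoxic list 5 of 14 members fell and none rose, with 10 lower adjusted over the list alone (camera adjusted p = 1.3e-07 with a preset correlation, adjusted p = 0.568 with an estimated correlation). Gzmb, the protease granzyme B, fell from 841.8 ± 442 to 68.7 ± 11.2 FPKM. Gzma fell from 84.9 ± 13.6 to 16.6 ± 5.81, Nkg7 from 448.3 ± 107 to 78.5 ± 15.6 and Fasl from 146.9 ± 36.5 to 48.4 ± 0.136 FPKM. Prf1, perforin, had 68.3 ± 22.6 against 19.1 ± 4.92 FPKM and an adjusted p of 0.0573. In the natural killer receptor list 7 of 23 members fell and none rose, 19 lower adjusted over the list alone (camera adjusted p = 4.6e-14, adjusted p = 0.568 with an estimated correlation). Klrd1 fell from 144.1 ± 32.1 to 31.4 ± 3.52 FPKM and Klrc1 from 20.8 ± 3.75 to 4.94 ± 0.427 FPKM. Members of the Klra family are near-identical, so their single values, as for Klra9, are uncertain. In the type 1 list 6 of 18 members fell and 1 rose (Il18r1), with 9 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.00663, adjusted p = 0.568 with an estimated correlation). Tbx21, the transcription factor T-bet, fell from 152.5 ± 45.8 to 27.0 ± 2.29 FPKM, Il12rb2 10.6-fold, Ccl5 6.76-fold and Cxcr3 3.59-fold. Beside these, Cd8a stood at 22.4 and 8.26 FPKM on the normal diet and 0.836 and 1.42 on the deficient diet, and Klrb1c, the gene of NK1.1, at 18.3 and 13.8 against 5.34 and 2.96 FPKM, neither past the threshold (adjusted p = 0.0604 for each). No member of the 3 lists passed without normal diet replicate 1 or either deficient diet replicate. Without normal diet replicate 2 the members that passed as lower were 6 cytotoxic, 8 natural killer receptor and 7 type 1 genes.

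Cell cycle genes were lower, by fitted value, in 36 of 36 members, and 18 passed over all genes tested and 34 adjusted over the list alone (camera adjusted p = 8.4e-26, adjusted p = 0.268 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell from 18.6 ± 1.01 to 2.69 ± 0.256 FPKM, Ube2c from 36.4 ± 4.29 to 5.37 ± 0.0129, Aurkb from 22.4 ± 4.72 to 1.87 ± 0.630 and Mki67 from 7.21 ± 1.61 to 1.10 ± 0.138. Of the interferon-stimulated genes 2 of 36 fell, Gbp3 (4.08-fold) and Ifi27l2a (10.5-fold, 17.4 and 26.7 against 2.99 and 1.22 FPKM). Adjusted over the list alone 12 were lower, and 34 were lower by fitted value (camera adjusted p = 2.2e-10, adjusted p = 0.268 with an estimated correlation). Without normal diet replicate 1 or either deficient diet replicate no member of these lists passed, and without normal diet replicate 2 the called members were 10 of 28 and 2 of 35. No ribosomal protein gene of 53 passed, over all genes or adjusted over the list alone, although the list was lower as a set (camera adjusted p = 1.8e-07, adjusted p = 0.781 with an estimated correlation) with a median log2 change of -0.45. The median was -0.26 without normal diet replicate 1 (camera adjusted p = 0.00248), -0.30 without deficient diet replicate 1 (0.00390) and -0.58 without normal diet replicate 2, where 1 of 49 members passed as lower. Many ribosomal protein genes were listed near 0, with 25 of 74 rows below a mean of 1 FPKM, and the values of these genes, many with near-identical copies, are uncertain. Of the 23 with a mean of at least 10 FPKM, a bound set after the values were seen, 22 were lower by fitted value, with a median of -0.42.

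**Figure D2:**
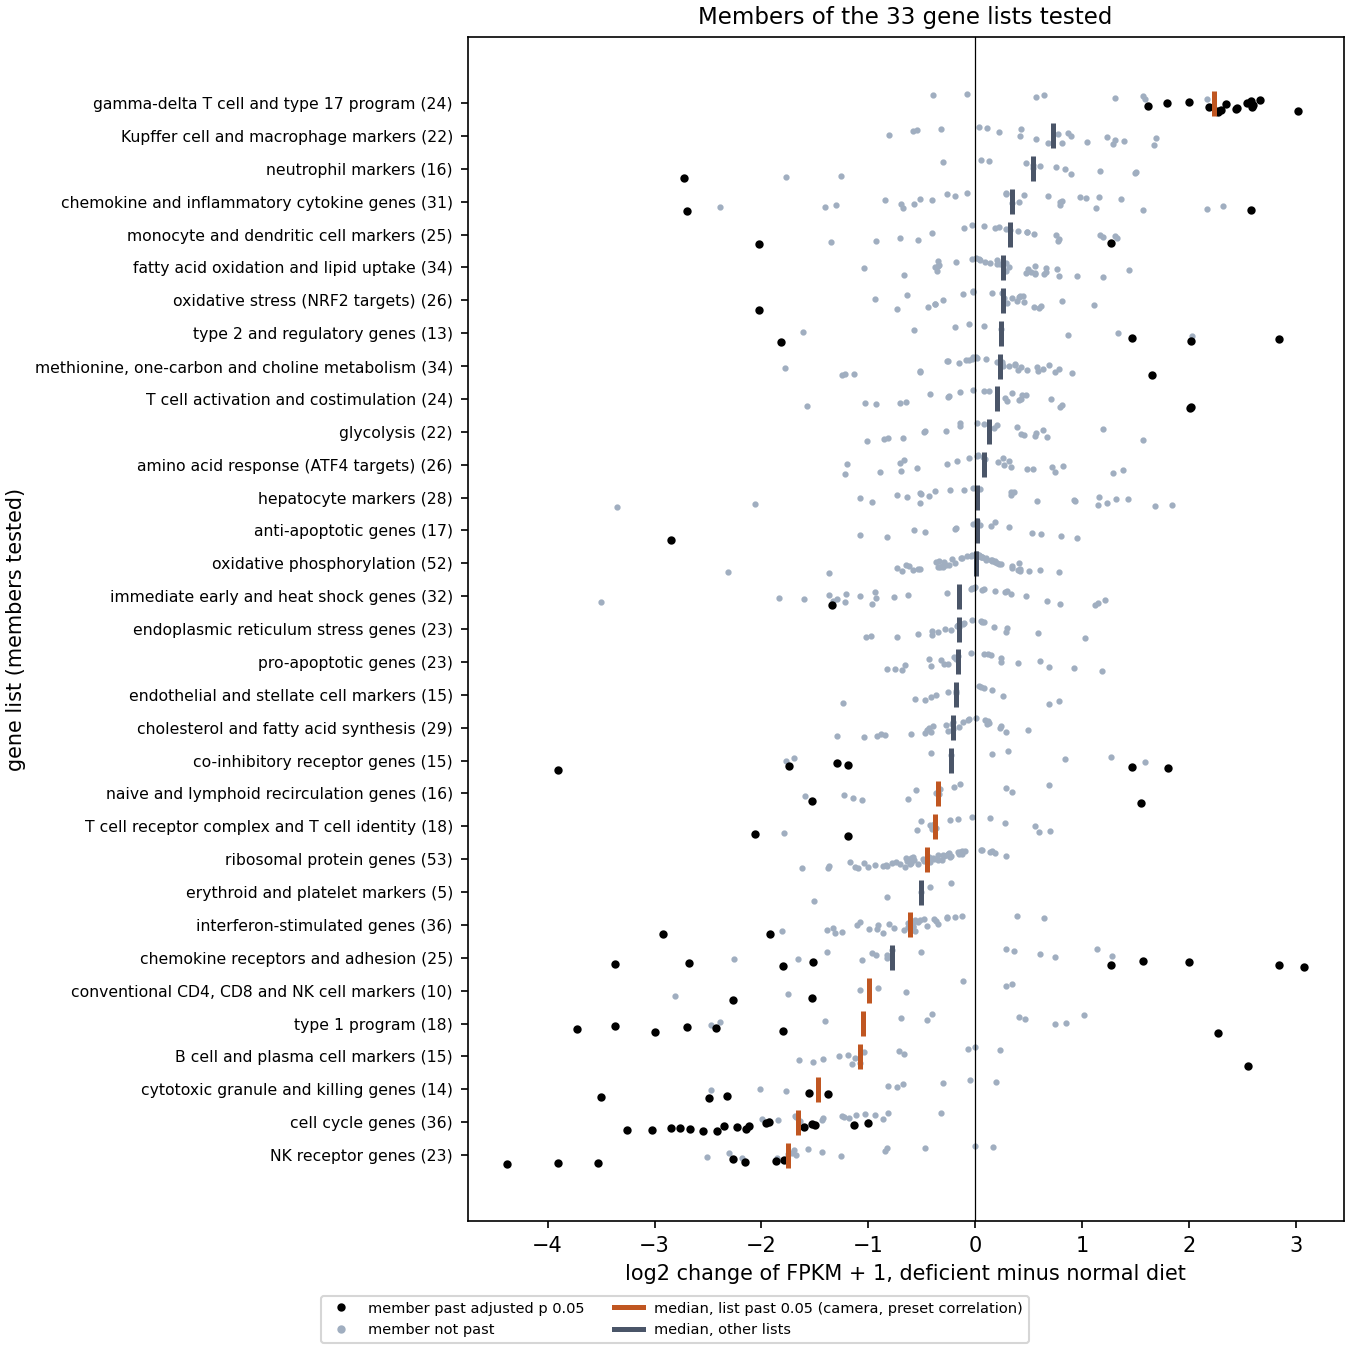
Log2 change of FPKM + 1 (deficient minus normal diet) of each member of the 33 gene lists tested, with black dots for members past an adjusted p of 0.05, grey dots for the others and a bar for each list's median, orange where the list passed camera with a preset correlation. The medians run from -1.76 for natural killer receptor genes to 2.23 for the type 17 list.

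In the other lists of T cell genes members went both ways. In the T cell identity list 2 of 18 fell and none rose, 4 lower and 2 higher adjusted over the list alone. Cd27, a costimulatory receptor, fell 2.31-fold and Ubash3a 4.61-fold. Cd3e had 404.1 ± 78.9 against 598.2 ± 144 FPKM, Thy1 122.5 ± 13.6 against 185.4 ± 10.3 and Trat1 37.6 ± 12.9 against 9.81 ± 0.118 FPKM, none of the 3 past the threshold. The naive and recirculation list had 1 rise, Il7r (154.6 ± 10.2 to 454.7 ± 6.90 FPKM), and 1 fall among 16, with 1 higher and 4 lower adjusted over the list alone. Ccr7 at 195.7 ± 12.6 against 93.6 ± 13.9 FPKM did not pass. Both lists were lower as sets (camera adjusted p = 0.0384 and 0.0382), lost with an estimated correlation (adjusted p = 0.862 and 0.568). The first was also lost without normal diet replicate 1 (0.349) or deficient diet replicate 1 (0.316) and the second without normal diet replicate 2 (0.143). Among 24 activation genes Icos (4.06-fold) and Il2ra (4.25-fold), the alpha chain of the interleukin 2 receptor, rose and none fell, with 3 higher and 1 lower adjusted over the list alone, and Nr4a1 did not pass. Of 15 co-inhibitory receptor genes Ctla4 and Nt5e rose and Cd160, Lag3, Tigit and Cd200r1 fell, 4 higher and 6 lower adjusted over the list alone. Of 25 chemokine receptor and adhesion genes 5 rose (Ccr8, Itgae, Ccr6, Ccr2 and Ccr4) and 4 fell (among them Itga1, Cxcr3 and Itga4), 8 higher and 11 lower adjusted over the list alone. Of 13 type 2 and regulatory genes 3 rose (Il2ra, Itgae and Ctla4) and 1 fell (Folr4, 3.83-fold), 5 higher and 1 lower adjusted over the list alone. These 4 lists did not pass camera as sets (adjusted p = 0.642, 0.493, 0.383 and 0.155). The activation list passed fry, which does not compare a list with other genes, as higher (adjusted p = 0.0323), and the type 2 and regulatory list passed camera without normal diet replicate 2 (adjusted p = 0.00874, median log2 change 0.89).

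With all 4 libraries and the filter of 1 FPKM, metabolic and stress lists did not pass camera as sets. Of 34 genes of methionine, one-carbon and choline metabolism 1 rose, Chdh, the choline dehydrogenase, from 4.89 ± 0.603 to 17.5 ± 0.795 FPKM, and it was also the only one adjusted over the list alone (camera adjusted p = 0.383). No gene passed, over all genes or adjusted over the list alone, among 34 of fatty acid oxidation and lipid uptake (camera adjusted p = 0.0743), where Acsl4 had 11.7 ± 2.22 against 27.7 ± 0.672 FPKM, among 29 of cholesterol and fatty acid synthesis (0.0916), 52 of oxidative phosphorylation (0.689), 23 of endoplasmic reticulum stress (0.191) or 23 pro-apoptotic genes (0.620). Of 17 anti-apoptotic genes Birc5 fell, 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.749), and Bcl2 at 81.2 ± 0.305 against 45.5 ± 2.71 FPKM did not pass (adjusted p = 0.0547). Birc5, survivin, is also a gene of dividing cells. Of 26 oxidative stress genes Osgin1 fell (117.9 ± 39.8 to 27.4 ± 1.51 FPKM), the only one adjusted over the list alone (0.789), and of 32 immediate early and heat shock genes Dusp2 fell (2.52-fold), with 5 higher and 8 lower adjusted over the list alone (0.179). None of 22 glycolysis genes passed over all genes, 1 higher and 3 lower adjusted over the list alone (0.925), and none of 26 amino acid response genes, 1 lower adjusted over the list alone (0.789). Of 31 chemokine and inflammatory cytokine genes Il17a rose and Ccl5 fell, 4 higher and 2 lower adjusted over the list alone (0.789), and Tnf had 122.2 ± 26.1 against 161.6 ± 21.5 FPKM. The median and the set test differed in sign for oxidative phosphorylation and anti-apoptotic genes, whose medians were 0.0085 and 0.011 and turned to -0.024 and -0.031 with quantile normalization. Without normal diet replicate 2 the cholesterol and fatty acid synthesis list passed as lower (camera adjusted p = 0.000155), as did immediate early and heat shock genes (0.0152) with a median of -0.10, and without deficient diet replicate 2 fatty acid oxidation passed with a median of 0.44 (0.0272). The chemokine and cytokine list passed without normal diet replicate 2 (0.00874, median 1.01, 7 members called higher), and its median was -0.40 without normal diet replicate 1. Trdc, a gene of the gamma-delta receptor, was not analysed here.

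Transcripts of cells that the sort should remove were present. The mean log2 value of macrophage markers was 1.30 and 3.32 in the normal diet libraries and 3.24 and 2.29 in the deficient diet libraries, and that of hepatocyte markers 1.00 and 2.85 against 2.23 and 1.66. Lyz2, a lysozyme of macrophages, stood at 140.4 and 1934 FPKM in the normal diet libraries and at 1197 and 662.7 in the deficient diet libraries, C1qa at 1.30 and 52.2 against 31.3 and 11.5, S100a8 at 17.7 and 357.0 against 128.4 and 146.8, and Clec4g, of sinusoidal endothelium, at 23.3 and 262.7 against 120.5 and 30.7. The other abundant markers of these types were Apoe, S100a9 and Fcgr2b, with log2 changes of 0.90, 0.47 and 0.04, none past the threshold. Cd74 and H2-Ab1, of antigen-presenting cells, had 418.7 ± 327 against 944.6 ± 543 and 317.5 ± 223 against 770.1 ± 476 FPKM. Hp and Trf, made by hepatocytes, had 35.3 ± 47.0 against 32.1 ± 7.54 and 13.4 ± 12.2 against 26.4 ± 6.71 FPKM, and Alb 9.11 ± 10.2 against 17.4 ± 7.19. Hba-a1 and Hbb-b2, globin genes, had log2 changes of -0.42 and -0.23. No list for hepatocytes (28 members), macrophages (22), monocytes and dendritic cells (25), neutrophils (16), endothelial and stellate cells (15) or erythroid cells (5) passed camera as a set with all 4 libraries (adjusted p = 0.843, 0.183, 0.795, 0.765, 0.795 and 0.322). The hepatocyte median was 0.013 and turned to -0.058 with quantile normalization. With 1 normal diet library left out, 5 of these lists passed in opposite directions. Without replicate 1 the medians were -1.03 for hepatocytes (camera adjusted p = 9.3e-05), -0.79 for macrophages (0.0461), -0.49 for monocytes and dendritic cells (0.0354), -1.09 for neutrophils (2.0e-08) and -1.58 for endothelial cells (3.1e-05). Without replicate 2 they were 1.29 (2.0e-06), 1.72 (2.5e-08), 1.14 (0.00291), 2.27 (4.6e-07, 8 members called higher) and 1.32 (0.00148), and erythroid genes passed with -1.66 (0.000712). Macrophage markers also passed without deficient diet replicate 2, with a median of 1.19 (0.0138). For neutrophils the test was lower and the median and mean higher. Called members were Ccr2 (higher) and Plac8 (lower) among monocyte genes and Mmp9 (lower) among neutrophil genes. Adjusted over the list alone, 1 monocyte gene was higher and 2 lower and 3 neutrophil genes were lower, and no gene of the other 4 lists passed. The B and plasma cell list was lower (camera adjusted p = 0.0384, adjusted p = 0.862 with an estimated correlation), but its 1 called member of 15, Sdc1, rose from 56.7 ± 9.61 to 333.2 ± 7.55 FPKM, with 1 higher and 3 lower adjusted over the list alone. Cd79b and Cd79a did not pass, and this list was lost without normal diet replicate 2 (0.735) and without deficient diet replicate 1 (0.220) or 2 (0.0681). The list of conventional CD4, CD8 and natural killer cell markers was lower (camera adjusted p = 0.00244, adjusted p = 0.568 with an estimated correlation), with 2 of 10 falling (Klra9 among them), 5 adjusted over the list alone. Cd4 had 3.99 ± 0.178 against 1.53 ± 1.29 FPKM and Cd40lg 237.1 ± 98.3 against 287.3 ± 21.3 FPKM.

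**Figure D3:**
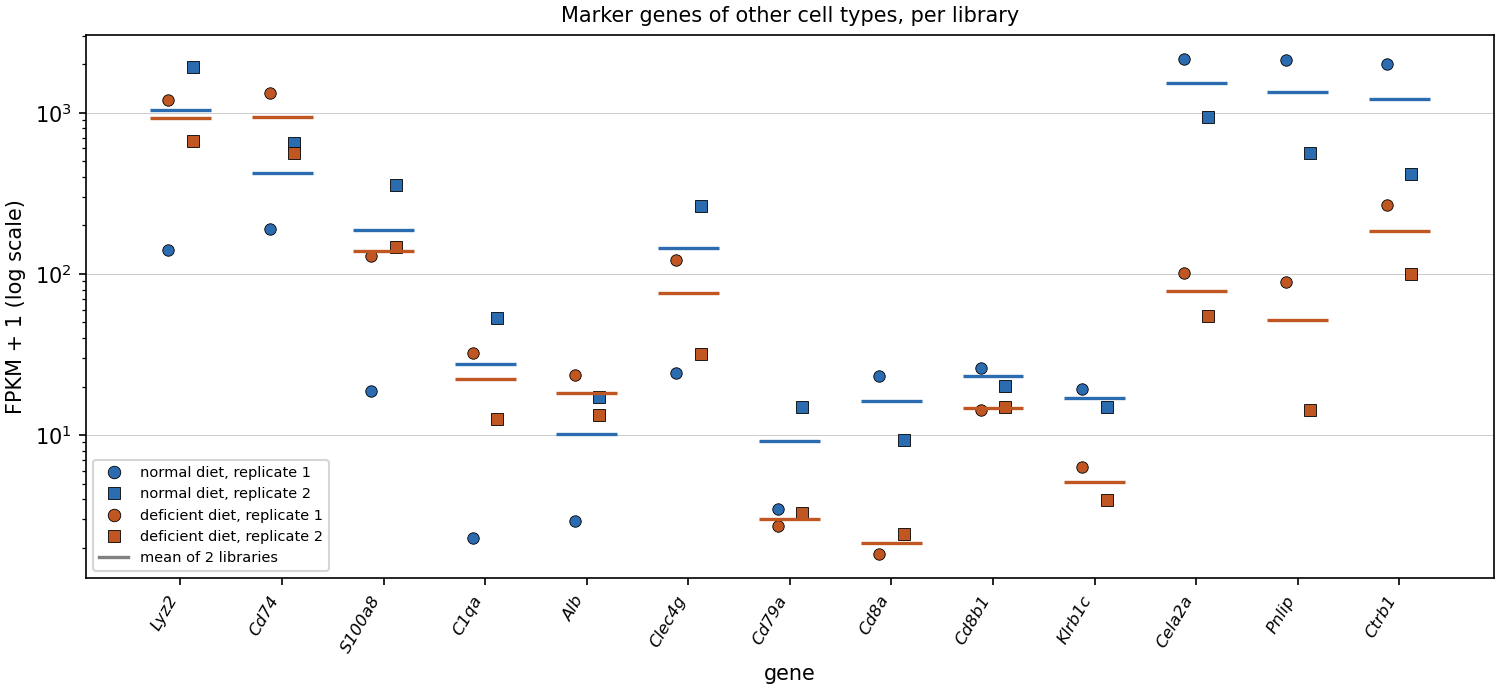
FPKM + 1 on a log axis for marker genes of other cell types in each library, with circles and squares for the libraries and a line for the mean of 2 libraries per diet. Normal diet replicate 1 is lowest for Lyz2, Cd74, S100a8, C1qa, Alb and Clec4g and highest for the pancreatic enzyme genes Cela2a, Pnlip and Ctrb1, where Pnlip stood at 2128 FPKM in that library and at 13.3 FPKM in deficient diet replicate 2.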

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

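Leaving out the genes of other cell types and robust empirical Bayes were chosen after seeing the data. The 286 calls (127 higher, 159 lower) became 467 with quantile normalization (205 and 262), 912 at an adjusted p of 0.10 (430 and 482), 141 without the trend (57 and 84), 448 without the genes of other cell types (199 and 249) and 432 with robust empirical Bayes (194 and 238). They became 0 (0 higher, 0 lower) in limma without a filter on low values, where 15857 genes were tested and 2712 had an unadjusted p under 0.05. Leaving out 1 library gave 0 to 352 calls, 0 to 207 higher and 0 to 145 lower, with the lone library of a diet assumed to vary like the others. In every setting run on all genes, each main call that was tested kept its direction. The libraries of the diets did not overlap for any of the 286, so most settings could not have turned a call. Only quantile normalization and centring on the median could have. The 1198 separated genes (500 higher, 698 lower) became 543 with a pseudocount of 5 (204 and 339) and 233 at a log2 change of 2 (75 and 158), and 460 to 909 were higher with 1 library left out. The 11 lists became 9 to 19 with 1 library left out, 1 to 8 of them higher, and 2 higher lists without a filter and with a filter of 5 FPKM. With an estimated correlation 0 lists passed (0 higher, 0 lower), with adjusted p of 0.268 for cell cycle and interferon-stimulated genes, 0.568 for type 17, cytotoxic, natural killer receptor, type 1, naive and conventional cell lists, 0.781 for ribosomal proteins and 0.862 for the T cell identity and B cell lists. With fry 3 lists passed, cell cycle and interferon-stimulated genes as 2 lower lists (0.0180) and, from outside the 11, T cell activation as higher (0.0323); the rest of the 11 had 0.0553 for natural killer receptors, 0.105 for type 17, cytotoxic and type 1, 0.170 for conventional cells, 0.243 for naive and ribosomal, 0.416 for T cell identity and 0.842 for B cells. The naive list had 0.0774 and the B cell list 0.411 with a filter of 5 FPKM, and T cell identity 0.0730 without the trend. Without 1 library T cell identity ran from 0.000712 to 0.349, the naive list from 0.0109 to 0.143 and the B cell list from 2.3e-08 to 0.735. With the replicate number as a replicate block, 0 genes were called (0 higher, 0 lower) and 1844 had an unadjusted p under 0.05. The block takes up a residual degree of freedom, so that fit has less power. The labels do not call the replicate number a pairing, and the deviations of the libraries numbered 1 correlated at -0.284 across genes.

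With 1 library left out, log2 changes ran from -1.40 (without normal diet replicate 1, where the direction turned) to 3.13 (without normal diet replicate 2) for C1qa, and likewise from -1.12 to 2.66 for Lyz2, -1.37 to 2.88 for S100a8, -1.33 to 2.27 for S100a9, -0.74 to 2.53 for Apoe, -1.09 to 3.40 for Hp, -0.66 to 1.12 for Cd79b and -1.64 to 1.71 for Fcgr2b. Hba-a1 ran from -1.66 without normal diet replicate 2 to 0.82 without normal diet replicate 1, and Hbb-b2 from -1.29 to 0.83. Clec4g ran from -2.09 without normal diet replicate 1 to 1.35 without normal diet replicate 2, with 0.60 without deficient diet replicate 2, and Cd40lg from 0.77 to -0.10. Without deficient diet replicate 1 Cd79b reached -0.0063 and Fcgr2b -0.94, and Fcgr2b had -0.0083 with a pseudocount of 5 and -0.0094 with quantile normalization. None of these genes had passed, and the cause was not tested. The unknown read depth limits what low values show, and no interval could be given for them. The alternatives for counts were not run, since the table holds none.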

Other observations

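The test on Cd8a and Cd8b1 and the requirement that a correlation hold within the ribosomal list were chosen after the result was seen, and the gene families here were not fixed beforehand. When the tested genes were grouped by the letters their symbols share, 316 families had at least 5 members, and 9 were lower and 0 higher on the deficient diet by camera with a preset correlation, none of them with an estimated correlation. The Gimap family, small GTPases of lymphocytes, was lower by fitted value in 8 of 8 members (camera adjusted p = 9.7e-05, adjusted p = 0.995 with an estimated correlation). The count of 8 was the same under each scaling tried, which could hardly have changed it. Quantile normalization and centring moved the median log2 change only from -0.82 to -0.85 and -0.79, and the smallest fall of a member was -0.37. Over all genes 2 members passed. Gimap7 was one, and Gimap4 stood at 1997 and 1388 FPKM on the normal diet and at 421.7 and 406.7 FPKM on the deficient diet. The other families were those of Mcm, Klra, Cdca, Kif, Gbp, Ifi, Rpl and Rps genes, which overlap the lists already described.

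Of genes of the exocrine pancreas, whose cells the sort should remove, 21 of 25 already seen and 6 of 12 not looked at before had both normal diet libraries above both deficient diet libraries, and others, such as Try4 and Try5, did not. Pnlip stood at 2128 and 559.3 FPKM on the normal diet and at 88.1 and 13.3 on the deficient diet, and Ctrb1 at 2012 and 413.1 against 268.0 and 98.3. A candidate source is RNA of acinar cells in the libraries. The prediction set beforehand was that more than 50 percent of acinar genes not looked at before follow the order of Cela2a over the 4 libraries. Of 12 such genes that reached 1 FPKM, 6 followed it, where chance gives 1 in 24 for each gene, so the bound was not reached. Acinar RNA does not by itself fix that order, so missing the bound cannot tell whether such RNA was present. By counts made afterwards, normal diet replicate 1 was highest in 11 of the 12 and in 25 of 25 already seen, Try4 and Try5 included. Acinar transcripts were thus in excess in that library, but their source stays open. Tissue carried along and reads from another library cannot be told apart here, and no biological explanation was tested.

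The lower cytotoxic, natural killer receptor and type 1 genes could reflect natural killer or CD8 T cells passing the gate in the normal diet libraries, although the sort removes NK1.1 and CD8 positive cells. Of natural killer genes already seen, 5 of the 7 that reached 1 FPKM had both normal diet libraries above both others, among them Ncr1 (0.898 and 3.39 FPKM against 0.173 and 0), while Tyrobp (0.772 and 3.87 against 2.29 and 2.30) and Fcer1g (21.7 and 53.2 against 26.6 and 22.3), which myeloid cells also express, did not. Klrb1c and Klra9, among the 5, are natural killer receptor genes themselves, so that tally is in part the pattern to be explained. Of natural killer genes not looked at before only 4 reached 1 FPKM. Of these 4, 2 had both normal diet libraries above the others (Samd3 among them, Osbpl5 not), too few to decide. Cd8a changed by -2.80 and Cd8b1 by -0.65 on the log2 scale, and neither passed the test. Against a median of -2.46 for the 18 called members that fell, Cd8a lay beyond it and Cd8b1 did not. That median covers only members that passed, which favours large falls. Cd8b1 stood at 25.2 and 19.3 FPKM on the normal diet and at 13.4 and 14.0 on the deficient diet. On the deficient diet Cd8a stood at 0.836 and 1.42 FPKM. With levels so unlike there, the comparison of log2 falls cannot decide on CD8 T cells. These sources and a change in the mix or state of T cells with diet, which was not tested, stay open.

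Many ribosomal protein genes were listed near 0. One candidate explanation is that reads shared with near-identical copies were not counted, which predicts higher FPKM for genes with more sequence of their own. Across 129 ribosomal protein and oxidative phosphorylation genes, the share of 36-base words found in no other gene correlated with mean FPKM (Spearman rho = 0.439, Pearson r = 0.410 with log2 values, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 6e-05 over 6 correlations), above the bound of 0.3 set beforehand; genes are not independent replicates. Within the ribosomal list rho was 0.243 (adjusted p = 0.0565) and within oxidative phosphorylation 0.245 (0.0769), so part of the pooled value is the difference between the lists. Transcript length, which could understate short genes, gave rho = 0.270 over both lists (Pearson r = 0.160 with log2 values, adjusted p of rho = 0.00627), between the bounds of 0.1 and 0.3 set beforehand for both lists together, and 0.318 within ribosomal genes (Pearson r = 0.12, adjusted p of rho = 0.0126), above the upper of these values by rank only, so both explanations stay open.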
